A study of Homo sapiens with 6 samples.

How the data were processed

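Gene expression was measured in COLO 205 cells, an established human colorectal adenocarcinoma cell line, with the Affymetrix Human Gene 2.0 ST array, per the labels' protocols. The series holds 6 arrays. Cells were kept for 24 h in 3 media, each with the vehicle DMSO or with TM5441, an inhibitor of plasminogen activator inhibitor 1 (PAI-1), per the labels. The media were fetal bovine serum (FBS), a patient-derived cell-free ascites with a low PAI-1 level and a patient-derived cell-free ascites with a high PAI-1 level. Each of the 6 conditions had 1 array, so each medium had 2 arrays and each inhibitor arm had 3. Each ascites medium was a single ascites sample, so a difference between the ascites media cannot be assigned to PAI-1 rather than to any other difference between those fluids.

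The deposited table of the authors holds 1 log2 value per probe set and array for 53617 probe sets. The base of the logarithm is not given in the sources used here. It was taken as 2 because scanner intensities are too small to give values this high with base e. R 3.4.2 was used by the authors, per the submitters' processing notes. Background correction, normalization and probe-set summarization are not given in the sources used here. The 6 arrays had medians between 3.54 and 3.61 and similar but unequal distributions. Their pairwise correlations across all probe sets lay between 0.990 and 0.994.

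Probe sets were named from the platform annotation, with symbols updated through their gene identifiers to the RefSeq annotation of assembly GRCh38.p14, in which all 16098 named probe sets were matched. Of the 53617 probe sets, 16098 had 1 gene, 0 had several genes and 37519 were unnamed here and entered no gene test. The named probe sets covered 14884 gene symbols, 779 of them with several probe sets, of which the one with the highest mean over the 6 arrays was used. Genes whose mean over the 6 arrays exceeded the median of the named probe sets, 4.66 on the log2 scale, were tested. A gene could pass through 1 medium alone. Differences from a medium whose mean lay below that level are less certain in size. These were MT1G, IFITM2 and MIR328 in FBS, MT1G in high-PAI-1 ascites, MIR4632 in low-PAI-1 ascites and ANXA13 in both ascites media. The level is not a detection limit, since the first quartiles of the arrays lay between 2.31 and 2.37. The filter left 7572 genes, of which 6939 were protein-coding and 197 were microRNA precursors. The build of the probe positions is not given in the sources used here, so no coordinates are printed, and the annotation was used only for names and for the order of neighbouring genes.

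Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values of all 6 arrays, with an additive model of medium and inhibitor. The model gave 4 tested comparisons: high-PAI-1 ascites against FBS, low-PAI-1 ascites against FBS, high-PAI-1 against low-PAI-1 ascites, and TM5441 against DMSO with medium as a block. It left 2 residual degrees of freedom, to which the moderation added 4.99. Its error term holds array noise together with any interaction of medium and inhibitor. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: the median standard error of a medium difference was 0.06 on the log2 scale and that of the TM5441 difference was 0.05. Comparisons of 1 array with 1 array, and differences of the TM5441 effect between media, are given as values with no test, with the count of genes at an absolute log2 difference of at least 1.

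The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. In each tested comparison the 8 genes with the highest and the 8 with the lowest difference were named, among genes past the threshold with the same sign in every matched pair of arrays. Where fewer passed, the largest differences with the same sign in every pair were named as values. In each single-array comparison the 5 highest and 5 lowest were eligible, and in each gene list up to 4 members with the largest absolute difference. Genes named outside this rule are other members of the fixed lists or neighbours of LCN2, and the neighbours were chosen after their values were seen. Of 42 gene lists, 34 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with adjustment over lists within a comparison. Camera sets a list against the other tested genes, so its sides are relative to them. The median of all tested genes was −0.07 for high-PAI-1 and −0.03 for low-PAI-1 ascites against FBS. It was −0.04 for high-PAI-1 against low-PAI-1 ascites and −0.03 for TM5441 against DMSO. No list was past the threshold with a correlation estimated from the data. That setting also makes camera use the 2 residual degrees of freedom, so hardly any list could pass, whatever its correlation. For the WNT and stem cell list in low-PAI-1 ascites against FBS the estimated correlation was −0.018, below the preset value. Its unadjusted camera p still went from 4.76e-06 to 0.0407. A loss of a call in that setting therefore does not show that gene correlation explains the result. Other lists had estimates above the preset value, such as 0.915 for metallothioneins, 0.566 for goblet genes and 0.292 for the integrated stress response. STAT3 targets had 0.277, interferon genes 0.253 and NF-kappaB targets 0.218, while chemokines had −0.318. These estimates rest on the 2 residual degrees of freedom. Where the preset value is too low, camera p-values are too small, so gene correlation stays possible for those lists.

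The alternatives were no expression filter, a filter at the 75th percentile, the mean over a gene's probe sets, quantile normalization, median centring, an intensity trend in eBayes, the model without its other factor, camera on ranks or with an estimated correlation, and leaving out each array in turn. Cyclic loess normalization was added after seeing the data. On simulated data for the 7572 genes with 200 changed genes, 99% of changes of 0.5 on the log2 scale were recovered for TM5441 against DMSO. The share was 81% for high-PAI-1 ascites against FBS, 90% for low-PAI-1 ascites against FBS and 95% for the ascites media against each other. Of changes of 1, 100%, 100%, 98% and 100% were recovered in the same order. Of the simulated calls, 6.57%, 4.74%, 6.00% and 5.34% were false in that order. These shares hold for the simulated data alone. In the real fit a TM5441 effect limited to a single medium would partly enter the error term. The shares therefore do not give the power for such an effect, nor the share of false calls among the real ones.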

Results

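Expression profiles were obtained from COLO 205 cells after 24 h in FBS, in low-PAI-1 ascites or in high-PAI-1 ascites, each with DMSO or with TM5441. Ascites is the fluid that collects in the peritoneal cavity, and PAI-1 is a secreted inhibitor of the plasminogen activators tPA and uPA. With 1 array per condition, each difference between media is the mean of 2 matched differences (n = 2 arrays per medium), and the TM5441 difference is the mean of 3 (n = 3 arrays per arm). Differences are on the log2 scale and are given with the standard error (SE) of the additive fit. Adjusted p-values come from limma. Every gene past the threshold in a comparison of media had the same sign in both matched pairs.

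The first comparison asked how high-PAI-1 ascites changed expression relative to serum. LCN2, which encodes a secreted siderophore-binding protein, rose by 3.04 ± 0.11 (8.25-fold, adjusted p = 0.00012). Complement factor B (CFB) rose by 1.24 ± 0.06, the neutrophil chemokine gene CXCL8 by 1.23 ± 0.12, IFITM2 by 1.18 ± 0.09 and the stress cytokine gene GDF15 by 1.16 ± 0.07. BAAT, which encodes the enzyme that conjugates bile acids to glycine and taurine, fell by 1.68 ± 0.07 (3.20-fold, adjusted p = 0.000296). The intestinal annexin gene ANXA13 fell by 1.24 ± 0.07, SESN1 by 1.11 ± 0.06, the gut epithelial gene PHGR1 by 1.05 ± 0.11 and the gluconeogenic enzyme gene PCK1 by 1.04 ± 0.06. Of 7572 genes, 1251 were past the threshold, 289 of them higher and 962 lower, with a median absolute difference of 0.31.

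Further genes that rose in high-PAI-1 ascites were the microRNA precursor gene MIR328 (0.98 ± 0.17, and 0.61 with adjusted p = 0.0557 without the FBS TM5441 array), the NF-kappaB cofactor gene BCL3 (0.88 ± 0.06) and PTGES2 (0.86 ± 0.06). Further genes that fell were CAPN6 (−1.04 ± 0.07), the water channel gene AQP1 (−0.95 ± 0.06) and the eosinophil chemokine gene CCL24 (−0.94 ± 0.07). The share of higher calls was 23.1%, and it was 39.6% after quantile normalization, 53.4% after cyclic loess normalization and 56.0% of 25 calls with no filter. The count of calls was 46 without the FBS DMSO array, 65 without the FBS TM5441 array, 505 without the high-PAI-1 DMSO array and 93 without the high-PAI-1 TM5441 array.

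In high-PAI-1 ascites members of several inflammatory lists rose. Of 9 tested STAT3 targets 5 rose, 0 fell and 4 did not pass, and 6 rose when adjusted over the list alone. LCN2 and BCL3 led them, followed by STAT3 itself (0.44 ± 0.06) and JUNB (0.35 ± 0.06). The list was past the camera threshold (adjusted p = 1.12e-06), with adjusted p = 0.393 with an estimated correlation. Of 9 tested targets of NF-kappaB and tumour necrosis factor 5 rose and 4 did not pass, and 6 rose when adjusted over the list alone. They were CXCL8, CXCL2 (0.59 ± 0.07), IRF1 (0.56 ± 0.06), CCL20 (0.52 ± 0.08) and ZC3H12A (0.45 ± 0.06). Camera gave adjusted p = 2.02e-06 for that list, and adjusted p = 0.393 with an estimated correlation. Of 4 tested chemokines, CXCL8, CXCL2 and CCL20 rose and CXCL16 (0.01 ± 0.06) did not pass, 3 also when adjusted over the list alone, and these 3 belong to the NF-kappaB list too. The chemokine list had adjusted p = 0.000191, and adjusted p = 0.393 with an estimated correlation. Of 12 tested interferon genes IRF9 (0.39 ± 0.09), IRF7 (0.27 ± 0.06) and ISG15 (0.23 ± 0.06) rose, 3 also when adjusted over the list alone, and the list was not past the camera threshold (median −0.10, adjusted p = 0.398).

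Genes of the integrated stress response, which the transcription factor ATF4 induces when amino acids are short or proteins misfold, also rose. Of 14 tested members 7 rose, 0 fell and 7 did not pass, and 9 rose when adjusted over the list alone. GDF15, DDIT4 (0.70 ± 0.06), TRIB3 (0.63 ± 0.06) and PCK2 (0.53 ± 0.07) had the largest differences. Camera gave adjusted p = 6.98e-10, and adjusted p = 0.393 with an estimated correlation. Of 11 tested WNT and stem cell genes 7 fell, 0 rose and 4 did not pass, with the same 7 as the count adjusted over the list alone. The intestinal stem cell marker LGR5 (−0.81 ± 0.07), SMOC2 (−0.53 ± 0.06) and the feedback inhibitor gene AXIN2 (−0.45 ± 0.07) led them. Camera gave adjusted p = 0.00307 for this list, and adjusted p = 0.393 with an estimated correlation. After cyclic loess normalization 3 members of the list fell.

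Of 5 tested goblet and secretory cell genes 4 fell and 1 did not pass, also when adjusted over the list alone. TFF3 fell by 0.52 ± 0.06, the transcription factor gene SPDEF by 0.42 ± 0.06, AGR2 by 0.40 ± 0.08 and TFF1 by 0.25 ± 0.06. The goblet list had camera adjusted p = 0.0142, and adjusted p = 0.576 with an estimated correlation. Of 17 tested cholesterol synthesis genes 3 rose, namely MVK (0.34 ± 0.06), DHCR7 (0.22 ± 0.06) and HMGCS1 (0.22 ± 0.06), and 5 rose when adjusted over the list alone. Camera gave adjusted p = 0.000523 for the list, and adjusted p = 0.393 with an estimated correlation. Of 9 tested fatty acid synthesis genes FASN rose (0.34 ± 0.07), the count being 1 also when adjusted over the list alone. That list had adjusted p = 0.00382, and adjusted p = 0.393 with an estimated correlation.

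**Figure D1:**
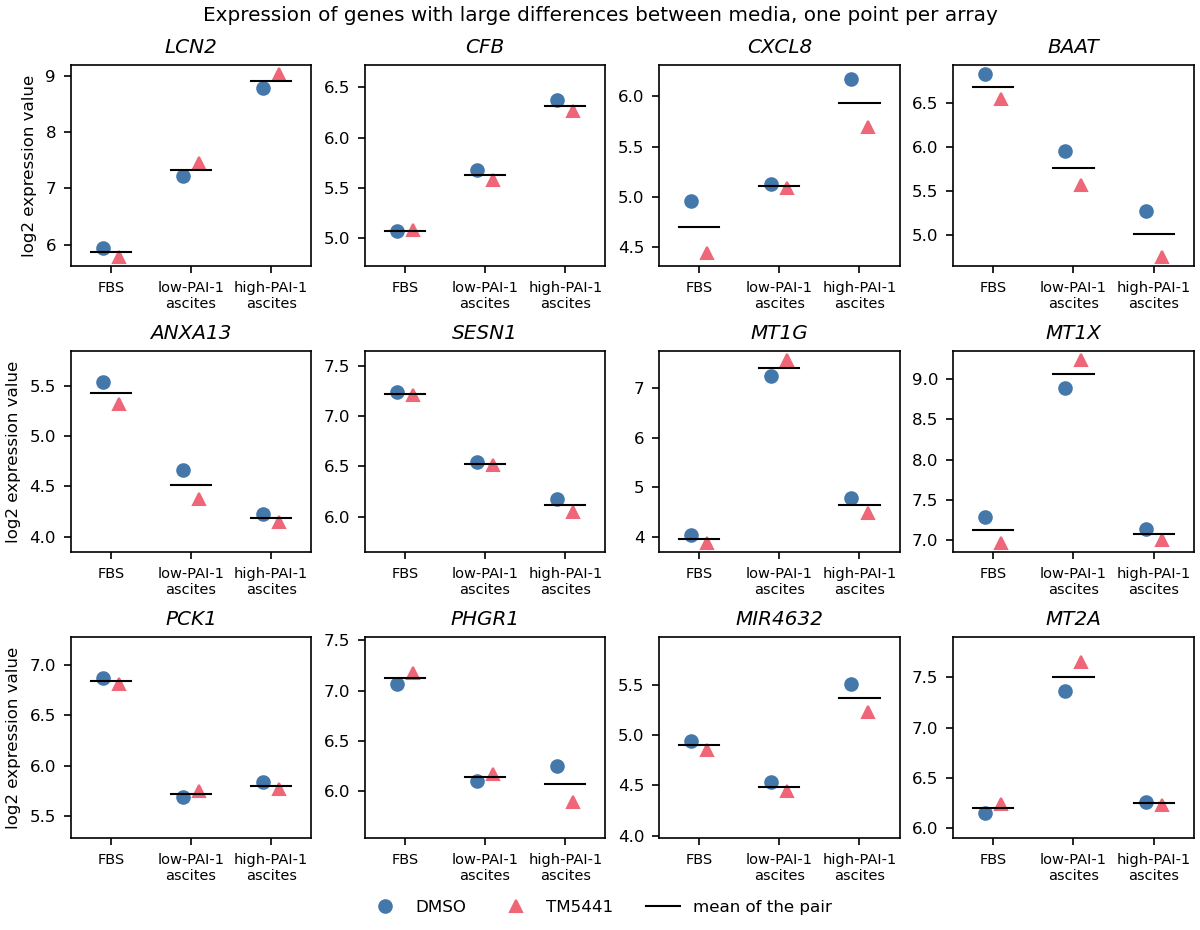
Log2 expression values (vertical axes) of 12 genes in the 3 media (horizontal axes), with 1 point per array, blue circles for DMSO, red triangles for TM5441 and a black line at the mean of each pair. LCN2 lay between 8.78 and 9.03 in high-PAI-1 ascites and between 5.78 and 5.95 in FBS, and MT1G lay between 7.24 and 7.56 in low-PAI-1 ascites and at most at 4.78 in the other media.

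In low-PAI-1 ascites, the highest rises over serum were those of MT1G and MT1X, which encode metal-binding metallothioneins. MT1G rose by 3.44 ± 0.13 (10.8-fold, adjusted p = 0.000274), with FBS values (4.05 and 3.88) below the filter level. MT1X rose by 1.94 ± 0.14 (3.85-fold) and MT2A by 1.31 ± 0.08. LCN2 rose by 1.47 ± 0.11, the netrin receptor gene UNC5B by 1.39 ± 0.14, DDIT4, which encodes an inhibitor of mTORC1, by 1.37 ± 0.06, the cytokine receptor gene IL20RB by 1.34 ± 0.09 and GDF15 by 1.33 ± 0.07. PCK1 fell by 1.13 ± 0.06 (2.18-fold), PHGR1 by 0.98 ± 0.11, BAAT by 0.93 ± 0.07, ANXA13 by 0.91 ± 0.07 and LGR5 by 0.88 ± 0.07. CCL24 fell by 0.85 ± 0.07, FGF18 by 0.80 ± 0.06 and PNPLA3 by 0.74 ± 0.08. Of 7572 genes, 293 were past the threshold, 151 of them higher and 142 lower, with a median absolute difference of 0.41.

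The share of higher calls in low-PAI-1 ascites was 51.5%, and it was 65.8% after cyclic loess normalization, 35.2% with the stricter filter, 37.8% with an intensity trend and 92.9% of 14 calls with no filter. The count of calls was 31 without the FBS DMSO array and 42 without the FBS TM5441 array. Probe sets of the near-identical metallothionein genes can share signal, so the division of the rise among MT1G, MT1X and MT2A is uncertain.

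Of 14 tested integrated stress response genes 12 rose in low-PAI-1 ascites, 0 fell and 2 did not pass, and 13 rose when adjusted over the list alone. The median difference of the list was 0.82. After DDIT4 and GDF15, the asparagine synthetase gene ASNS (1.16 ± 0.10), PCK2 (1.03 ± 0.07), TRIB3 (1.03 ± 0.06), the serine synthesis gene PSAT1 (0.97 ± 0.10) and PHGDH (0.67 ± 0.07) were among those that rose. ATF4 (0.13 ± 0.06) and ATF5 (0.24 ± 0.07) did not pass. Camera gave adjusted p = 3.06e-21, and adjusted p = 0.550 with an estimated correlation. Of 4 tested metallothioneins 3 rose and MT1F (0.20 ± 0.08) did not pass, and 4 rose when adjusted over the list alone. That list had adjusted p = 1.85e-07, and adjusted p = 0.550 with an estimated correlation.

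Of 17 tested cholesterol synthesis genes 7 fell in low-PAI-1 ascites, 0 rose and 10 did not pass, and 12 fell when adjusted over the list alone. MSMO1 fell by 0.66 ± 0.06, the sterol sensor gene INSIG1 by 0.59 ± 0.08, IDI1 by 0.47 ± 0.08 and SQLE by 0.42 ± 0.06. Camera gave adjusted p = 1.14e-06, and adjusted p = 0.550 with an estimated correlation. FASN fell by 0.48 ± 0.07, while the list of 9 fatty acid synthesis genes was not past the camera threshold (adjusted p = 0.261). Of 11 tested WNT and stem cell genes LGR5, SMOC2 (−0.67 ± 0.06) and SOX9 (−0.32 ± 0.06) fell and 8 did not pass, and 8 fell when adjusted over the list alone. That list had adjusted p = 4.05e-05, and adjusted p = 0.550 with an estimated correlation. Of 9 tested STAT3 targets LCN2 alone rose, 2 when adjusted over the list alone (camera adjusted p = 0.00871, and adjusted p = 0.575 with an estimated correlation). Of 9 tested NF-kappaB targets IRF1 alone rose (0.46 ± 0.06), 4 when adjusted over the list alone (camera adjusted p = 0.0299, 0.112 on ranks, and adjusted p = 0.575 with an estimated correlation).

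**Figure D2:**
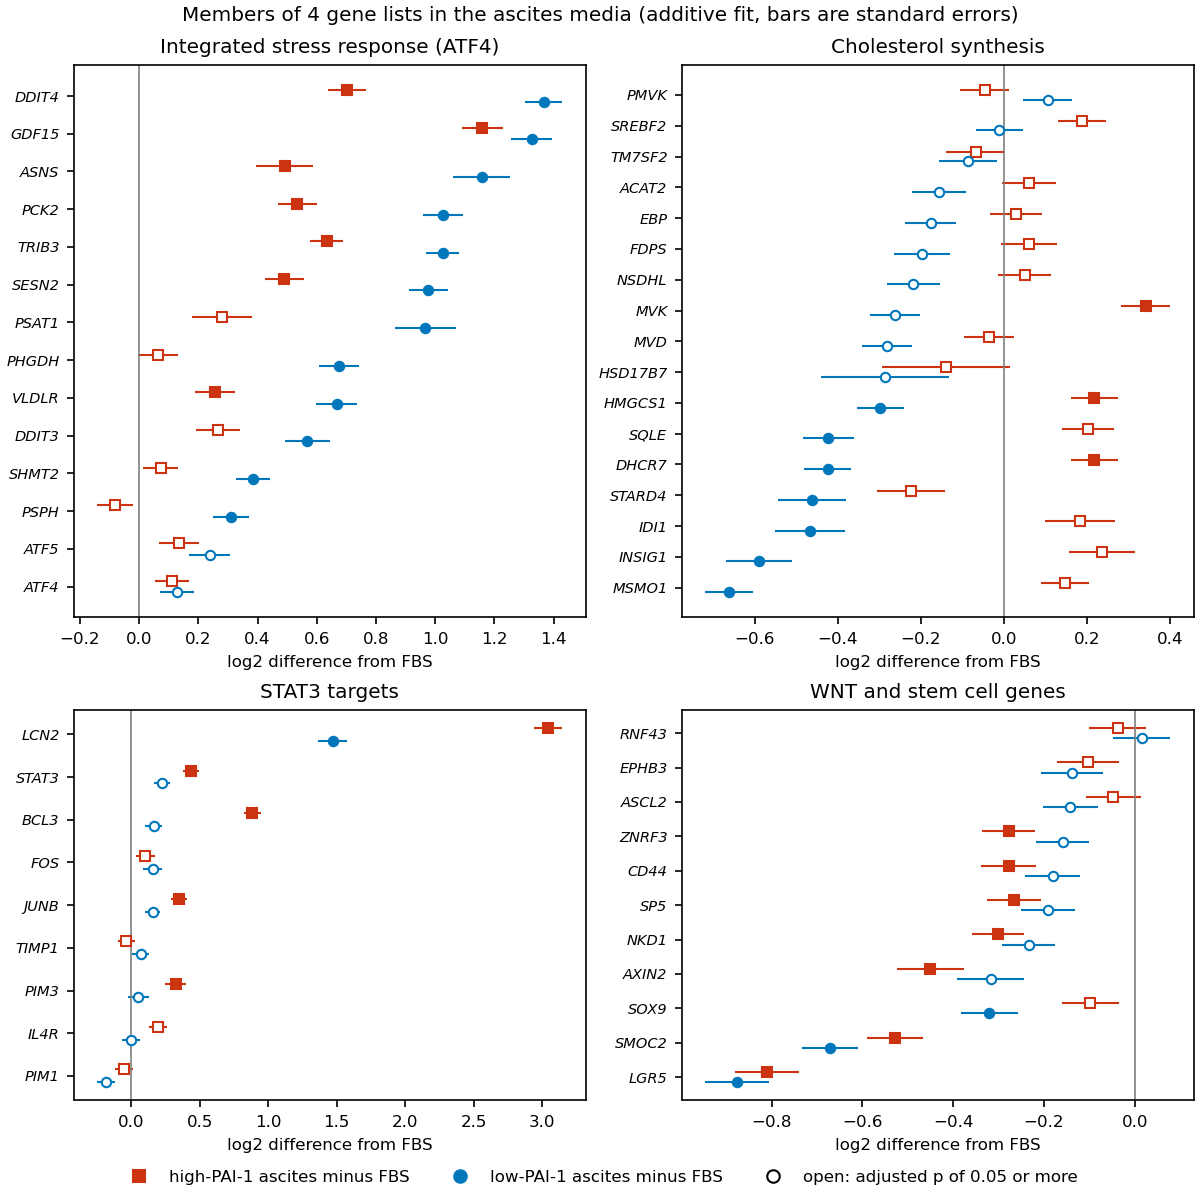
Log2 differences from FBS (horizontal axes) of the tested members of 4 gene lists (vertical axes), red squares for high-PAI-1 and blue circles for low-PAI-1 ascites, with bars for the SE of the additive fit and open symbols for an adjusted p of 0.05 or more. Of 14 integrated stress response genes 12 rose in low-PAI-1 and 7 in high-PAI-1 ascites. Of 17 cholesterol synthesis genes 7 fell in low-PAI-1 and 3 rose in high-PAI-1 ascites. Of 9 STAT3 targets 1 rose in low-PAI-1 and 5 in high-PAI-1 ascites. Of 11 WNT and stem cell genes 3 fell in low-PAI-1 and 7 in high-PAI-1 ascites.

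The ascites media were then compared with each other, the contrast that the PAI-1 levels define. In high-PAI-1 relative to low-PAI-1 ascites, LCN2 was higher by 1.57 ± 0.11 (2.98-fold, adjusted p = 0.00209), CXCL8 by 0.83 ± 0.12, INSIG1 by 0.82 ± 0.08, FASN by 0.82 ± 0.07 and MSMO1 by 0.81 ± 0.06. MIR4632 (0.88 ± 0.07), IFITM2 (0.76 ± 0.09) and BCL3 (0.72 ± 0.06) were also higher. MT1G was lower (−2.76 ± 0.13, 6.79-fold, adjusted p = 0.00123), as were MT1X (3.99-fold) and MT2A (−1.26 ± 0.08). So were IL20RB (−1.21 ± 0.09) and the adhesion molecule gene CEACAM6 (−1.08 ± 0.13). UNC5B (−0.94 ± 0.14), the matrix protein gene TNC (−0.91 ± 0.09) and the antisense transcript CLDN10-AS1 (−0.91 ± 0.07) were lower too. Of 7572 genes, 395 were past the threshold, 89 of them higher and 306 lower.

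The share of calls higher in high-PAI-1 than in low-PAI-1 ascites was 22.5%, and it was 33.1% after quantile normalization and 38.8% after cyclic loess normalization. The count of calls was 0 without the high-PAI-1 TM5441 array, where the smallest adjusted p among the named genes was 0.0536 (MT1G), 90 without the high-PAI-1 DMSO array, 168 without the low-PAI-1 TM5441 array and 151 without either FBS array.

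Of 17 tested cholesterol synthesis genes 7 were higher in high-PAI-1 than in low-PAI-1 ascites, 0 lower and 10 did not pass. Adjusted over the list alone, 14 were higher and 1 was lower. INSIG1, MSMO1, IDI1 (0.65 ± 0.08) and DHCR7 (0.64 ± 0.06) had the largest differences, and camera gave adjusted p = 8.62e-14, and adjusted p = 0.481 with an estimated correlation. FASN, ACSS2 (0.42 ± 0.08) and SCD (0.29 ± 0.06) were higher among 9 tested fatty acid synthesis genes, 5 when adjusted over the list alone. That list had adjusted p = 0.00058, and adjusted p = 0.481 with an estimated correlation. Of 14 tested integrated stress response genes 10 were lower, 0 higher and 4 did not pass, and 11 were lower when adjusted over the list alone. PSAT1 (−0.69 ± 0.10), ASNS (−0.67 ± 0.10), DDIT4 (−0.66 ± 0.06) and PHGDH (−0.61 ± 0.07) led them, with adjusted p = 6.5e-08 by camera, and adjusted p = 0.481 with an estimated correlation. All 4 tested metallothioneins were lower, also when adjusted over the list alone, with adjusted p = 2.63e-06 by camera, and adjusted p = 0.481 with an estimated correlation.

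Of 4 tested chemokines CXCL8, CCL20 (0.44 ± 0.08) and CXCL2 (0.36 ± 0.07) were higher in high-PAI-1 than in low-PAI-1 ascites, the same 3 as the count adjusted over the list alone (camera adjusted p = 0.000103, and adjusted p = 0.481 with an estimated correlation). These 3 were also the NF-kappaB targets that passed among 9 tested, where 5 passed when adjusted over the list alone (camera adjusted p = 2.62e-05, and adjusted p = 0.481 with an estimated correlation). LCN2 and BCL3 were higher among 9 tested STAT3 targets, 6 when adjusted over the list alone (camera adjusted p = 2.16e-05, and adjusted p = 0.481 with an estimated correlation). TFF1 (−0.81 ± 0.06), TFF3 (−0.36 ± 0.06) and AGR2 (−0.36 ± 0.08) were lower among 5 tested goblet cell genes, 3 also when adjusted over the list alone (camera adjusted p = 0.00888, and adjusted p = 0.681 with an estimated correlation). TFF1 went opposite ways against FBS, since it rose by 0.56 ± 0.06 in low-PAI-1 ascites and fell in high-PAI-1 ascites.

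The inhibitor arm asked whether TM5441 changed expression. No gene was past the threshold for TM5441 against DMSO over the 3 media (0 of 7572, limma with medium as a block, smallest adjusted p = 0.543), and 532 genes had an unadjusted p under 0.05 where 378.6 would be the number with no effect. The 3 other splits with 1 array of each medium on each side gave 267, 272 and 406. The largest difference was 0.45 ± 0.09 for the microRNA precursor gene MIR1226, whose DMSO values (4.24, 4.60 and 4.54) lay below the filter level. It was followed by MIR539 (0.40 ± 0.09), MIRLET7D (0.36 ± 0.06), MIR596 (0.35 ± 0.05) and ZNF354A (0.34 ± 0.07). On the lower side were BAAT (−0.39 ± 0.06), MIR4640 (−0.39 ± 0.07), ZNF613 (−0.35 ± 0.06), LINC03033 (−0.35 ± 0.08), CXCL8 (−0.35 ± 0.09) and NUDT2 (−0.33 ± 0.05). All of these had the same sign in the 3 media and none passed. For CXCL8 the low-PAI-1 values were close (5.13 under DMSO and 5.09 under TM5441), and its FBS TM5441 value (4.44) lay below the filter level. Without either low-PAI-1 array the count was 7, 3 higher and 4 lower, among them CXCL8 (−0.50), MIR4640 (−0.49) and LINC03033 (−0.46).

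Among gene lists, the PPAR lipid handling list had the lowest camera p for TM5441 (7 tested genes, median 0.11, adjusted p = 0.000283), and adjusted p = 0.702 with an estimated correlation. PLIN2 (0.18 ± 0.09), CREB3L3 (0.17 ± 0.05) and ANGPTL4 (0.15 ± 0.07) had its largest differences. The integrated stress response list (median 0.04, adjusted p = 0.000437), the iron list (median 0.09, adjusted p = 0.00475), the enterocyte list (median 0.04, adjusted p = 0.00535), the cholesterol list (median 0.02, adjusted p = 0.0286), the NRF2 list (median 0.03, adjusted p = 0.0286) and the NF-kappaB list (median 0.07, adjusted p = 0.0292, 0.0620 on ranks) were also past the threshold on the higher side. The interferon list (median −0.07, adjusted p = 0.0321, 0.0668 on ranks) and the goblet list (median −0.07, adjusted p = 0.0429, 0.0749 on ranks) were past it on the lower side. All 8 of these had adjusted p = 0.702 with an estimated correlation. No member of any of the 9 lists passed over all genes. Adjusted over the list alone, 1 iron gene was higher and 1 goblet gene was lower, and in the other 7 lists none passed. In the NF-kappaB list the member with the largest difference, CXCL8 (−0.35 ± 0.09), lay on the lower side, and the list mean was 0.02. Within media (no test), the interferon median was −0.01 in FBS, −0.11 in low-PAI-1 and −0.14 in high-PAI-1 ascites. In that order the integrated stress response had 0.09, 0.06 and −0.03. NRF2 had −0.03, 0.03 and 0.07, and cholesterol −0.01, 0.01 and 0.06. All tested genes had median −0.03 in FBS. The goblet median was negative, and the PPAR, iron, enterocyte and NF-kappaB medians positive, in each medium.

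Within each medium the TM5441 and DMSO arrays differed by less than 1 on the log2 scale for every tested gene, with no replicate check. In FBS the extremes were MIR1226 (0.72) and EIF5A (−0.60), in low-PAI-1 ascites MIR4742 (0.69) and MIR30E (−0.99), and in high-PAI-1 ascites PRM2 (0.77) and SCARNA3 (−0.80). Across genes, which are not independent replicates, the TM5441 differences correlated at r = 0.04 between FBS and low-PAI-1 ascites (Spearman's rho 0.03), 0.08 between FBS and high-PAI-1 ascites (rho 0.07) and 0.02 between the ascites media (rho 0.02). The medium differences measured under DMSO and under TM5441 correlated at r = 0.66 for high-PAI-1 ascites against FBS (rho 0.60), 0.64 for low-PAI-1 ascites against FBS (rho 0.53) and 0.55 for the ascites media against each other (rho 0.48).

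**Figure D3:**
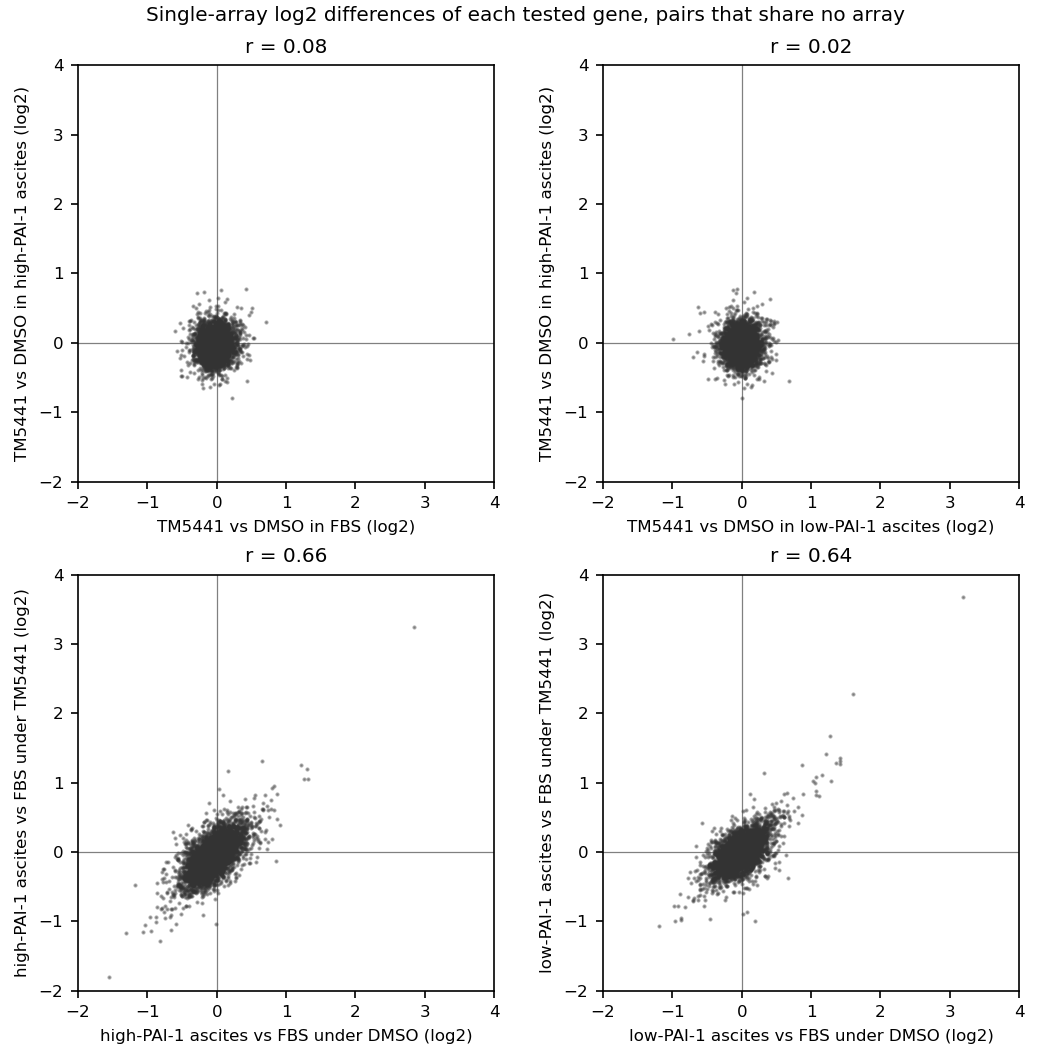
Each point is 1 of the 7572 tested genes, and both axes give log2 differences between single arrays, with no array shared between the axes of a panel. The TM5441 differences of separate media (upper panels) correlated at r = 0.08 and 0.02, and the ascites differences measured under DMSO and under TM5441 (lower panels) at r = 0.66 and 0.64.

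Genes called in high-PAI-1 ascites against FBS had a median absolute difference of 0.30 under DMSO and 0.33 under TM5441, and 42.7% of the 1251 genes had a smaller difference under TM5441. For low-PAI-1 ascites the medians were 0.42 and 0.41, with 53.2% of 293 genes smaller under TM5441. For the ascites media against each other the medians were 0.35 and 0.40, with 33.4% of 395 genes smaller under TM5441. That share was 49.4% of the 89 higher calls and 28.8% of the 306 lower calls. For high-PAI-1 ascites against FBS it was 50.9% of 289 higher and 40.2% of 962 lower calls. For low-PAI-1 ascites against FBS it was 45.7% of 151 higher and 61.3% of 142 lower calls. With 1 array per condition these differences between arms were not tested. The median of all tested genes moved between arms too. For the ascites media against each other it was −0.025 under DMSO and −0.058 under TM5441. It was −0.063 and −0.073 for high-PAI-1 ascites against FBS, and −0.037 and −0.016 for low-PAI-1 ascites against FBS. The shares among lower calls went the same way, so they cannot be told apart from a shift of whole arrays.

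The 2 ascites effects were compared on separate arrays, so that they shared no FBS array. High-PAI-1 against FBS under DMSO and low-PAI-1 against FBS under TM5441 correlated at r = 0.41 across genes (rho 0.34), and the opposite choice of arms gave 0.41 (rho 0.37). Of 16 plasminogen system genes 7 had a named probe set, of which ANXA2, LRP1, S100A10 and TFPI were above the expression filter, and the other 9 were not analysed here. LRP1, which encodes an endocytic receptor that binds PAI-1 complexes, was lower in high-PAI-1 than in low-PAI-1 ascites (−0.28 ± 0.06), and no other member passed in any comparison. Adjusted over the list alone, that was again the 1 call, and the list was past the camera threshold in no comparison (smallest adjusted p = 0.147).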

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

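The splits of the arrays and the cyclic loess test were chosen only after the result was seen. The values of the first items come from single arrays and were not tested. The TM5441 effect differed between media by at least 1 on the log2 scale for 2 genes between high-PAI-1 ascites and FBS, 4 between high-PAI-1 and low-PAI-1 ascites and 2 between low-PAI-1 ascites and FBS. MIR612 differed by 1.003 between high-PAI-1 ascites and FBS (0.72 and −0.28) and SCARNA3 by −1.03 (−0.80 and 0.23). Among the 4 between high-PAI-1 and low-PAI-1 ascites, MIR29C differed by 1.13 (0.51 and −0.62), MIR30E by 1.04 (0.05 and −0.99) and MIR4742 by −1.23 (−0.55 and 0.69). Between low-PAI-1 ascites and FBS MIR30E differed by −1.20 (−0.99 and 0.20) and TRIM74 by −1.04 (−0.54 and 0.50). Among 9704 unnamed probe sets above the filter, 4 were higher by at least 1 in high-PAI-1 ascites than in FBS in both arms, 2 were lower, and 7 were higher and 1 lower in low-PAI-1 ascites. Between TM5441 and DMSO, 0 were higher and at most 1 was lower by as much in any pair of media.

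For TM5441, all 10 splits of the 6 arrays into 3 and 3 were fitted. The real split had 0 genes past the threshold and the highest other split had 0, so 10 of 10 had as many. Every split has at least as many as 0, so this count cannot decide anything. Besides, 10 splits are too few for a share under 0.05. With medium as a block, 6 of the 10 put both arrays of a medium on the same side and rest on 1 pair of arrays, so only 4 have the form of the real comparison.

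High-PAI-1 ascites gave more lower than higher calls (962 and 289, 23.1% higher). After quantile normalization 39.6% of calls were higher, and in fits without 1 array the share reached 57.1% (of 7 calls, without the high-PAI-1 TM5441 array), where 38.7% were higher in the same fit with no normalization, which leaves an array-wide difference in distribution open. After cyclic loess normalization 53.4% were higher, and up to 63.0% (of 27 calls) without the FBS TM5441 array, where 35.4% were higher with no normalization, so an intensity-dependent bias between arrays may account for the excess of lower calls. That method takes rises and falls to balance at each intensity, so a real excess could also be removed by it.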

How the results depend on the processing

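No gene call turned to the opposite sign in any alternative in which the gene was tested, and no list reversed in the alternatives in which lists were run, which leave out the intensity trend and the model without its other factor. For high-PAI-1 ascites against FBS the count was 1251, and it was 25 with no filter, 796 after cyclic loess (added after seeing the data), 2052 with an intensity trend, and between 46 and 1714 with 1 array left out. MIR328 lost its call without the FBS TM5441 (adjusted p = 0.0557), high-PAI-1 DMSO (0.0564) or high-PAI-1 TM5441 array (0.118), and PHGR1 without the FBS TM5441 array (0.0552). For low-PAI-1 ascites against FBS the count was 293, and it was 14 with no filter, 713 with the stricter filter, 990 with a trend, and between 31 and 270 with 1 array left out. UNC5B (0.0509) and PNPLA3 (0.0706) lost their calls without the FBS DMSO array and PHGR1 (0.0759) without the FBS TM5441 array. For the ascites media against each other the count was 395, and it was 2 with no filter, 700 with the stricter filter, 248 after quantile normalization, 214 after cyclic loess, 1065 with a trend, and between 0 and 391 with 1 array left out. For TM5441 it was 0, and between 0 and 7 with 1 array left out. Of the 1251, 293 and 395 calls, cyclic loess kept 653, 247 and 207, and a trend kept 1180, 290 and 380. With no filter, 13 named genes kept and 3 lost their calls for high-PAI-1 ascites against FBS. For low-PAI-1 ascites against FBS 8 kept and 8 lost them, and for the ascites media against each other 1 kept and 15 lost them. Leaving out an array leaves 1 array in a medium and 1 residual degree of freedom, so its array is taken to vary like the others. No paired analysis by replicate number was possible, because the labels give no replicate numbers.

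Single-array counts at an absolute log2 difference of at least 1 were 2, 2 and 5 for TM5441 in FBS, low-PAI-1 and high-PAI-1 ascites with no filter. Under DMSO they were 11 for low-PAI-1 ascites against FBS with the stricter filter, 16 with no filter and 3 with the stricter filter for high-PAI-1 ascites against FBS, and 13 and 3 for the ascites media. Differences of the TM5441 effect numbered 36 (high-PAI-1 minus FBS), 44 (high-PAI-1 minus low-PAI-1) and 28 (low-PAI-1 minus FBS) with no filter, and 0 in each with the stricter filter. Correlations across genes between arms were, with no filter, 0.326 for low-PAI-1 against FBS, 0.450 for high-PAI-1 against FBS and 0.335 for the ascites media. The 2 pairings of the high-PAI-1 with the low-PAI-1 effect across arms gave 0.214 and 0.249. With the stricter filter the values were 0.789, 0.762, 0.669, 0.524 and 0.495 in the same order. None of these pairs shared an array. Lists past the camera threshold were 0 in all 4 comparisons with an estimated correlation, 0 for TM5441 with no filter, 5 (TM5441), 7, 7 and 7 with the stricter filter, and between 2 and 9 for TM5441 with 1 array left out. Camera on ranks kept 12 of 12 lists for high-PAI-1 ascites against FBS, 9 of 12 for low-PAI-1 ascites against FBS, 9 of 11 for the ascites media and 6 of 9 for TM5441. It ended the calls of NF-kappaB (adjusted p = 0.112), hypoxia (0.0920) and NRF2 (0.134) in low-PAI-1 ascites against FBS. It also ended those of iron (0.214) and MAPK (0.0661) between the ascites media, and of NF-kappaB (0.0620), interferon (0.0668) and goblet (0.0749) for TM5441.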

Other observations

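In low-PAI-1 ascites the chaperone genes HSPH1 (−0.51 ± 0.06) and HSPB1 (−0.29 ± 0.06) fell among 7 tested heat shock genes, 5 when adjusted over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.550 with an estimated correlation). In the same medium VEGFA rose by 0.48 ± 0.06 and DDIT4 rose among 12 tested hypoxia genes, 4 when adjusted over the list alone (camera adjusted p = 0.0088, and adjusted p = 0.550 with an estimated correlation). IRF9 (0.59 ± 0.09) rose among 12 tested interferon genes, 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.575 with an estimated correlation). ETFDH (0.33 ± 0.06) rose among 7 tested PPAR genes, 1 also when adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.550 with an estimated correlation). Of 25 tested G1/S genes, CDT1 (0.45 ± 0.06), CDC6 (0.39 ± 0.07), CCNE2 and EXO1 rose and CDCA7 (−0.59 ± 0.06) fell, 4 and 2 when adjusted over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.656 with an estimated correlation). SRXN1 (0.40 ± 0.06) and HMOX1 (0.39 ± 0.06) rose among 8 tested NRF2 targets, 2 also when adjusted over the list alone (camera adjusted p = 0.0484, and adjusted p = 0.655 with an estimated correlation).

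In high-PAI-1 ascites SRXN1 (0.41 ± 0.06) and PGD (0.27 ± 0.06) rose among 8 tested NRF2 targets, 3 when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.487 with an estimated correlation). LCN2 was the 1 of 4 tested iron genes that rose, 3 when adjusted over the list alone (camera adjusted p = 0.000279, and adjusted p = 0.393 with an estimated correlation). CDC6 and CDT1 rose and CDCA7 (−0.77 ± 0.06) and GINS2 fell among 25 tested G1/S genes, 2 and 2 also when adjusted over the list alone (camera adjusted p = 0.00655, and adjusted p = 0.641 with an estimated correlation). AMOTL2 (0.28 ± 0.07) rose among 3 tested YAP targets, 2 when adjusted over the list alone (camera adjusted p = 0.0142, and adjusted p = 0.393 with an estimated correlation). Between the ascites media the ribosomal protein list had median 0.06 with 0 of 15 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.00312, and adjusted p = 0.681 with an estimated correlation). ETV4 (0.34 ± 0.07) was higher in high-PAI-1 than in low-PAI-1 ascites among 12 tested MAPK targets, 1 also when adjusted over the list alone (camera adjusted p = 0.0376, and adjusted p = 0.831 with an estimated correlation). LCN2 was the 1 iron gene higher there, 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0155, and adjusted p = 0.481 with an estimated correlation). Lists past the threshold in no comparison numbered 14 (smallest adjusted p = 0.106), namely the plasminogen system, glycolysis, LXR, the unfolded protein response, p53, G2/M, MYC ribosome biogenesis, TGF-beta, epithelial junctions, matrix proteases, glucocorticoid targets, apoptosis, oxidative phosphorylation and mesothelial markers. A further 8 lists had too few tested genes, namely class I antigen presentation, mesenchymal transition, AHR, macrophage, lymphocyte, fibroblast, erythroid and platelet markers, and histones. Of the cell-type markers, LYZ (mean 11.1), CD68 (11.4) and MSLN (6.81) had high values in all media, and of the 30 named cell-type markers 8 were above the filter and tested, of which 0 passed in any comparison by limma. No fibroblast marker was tested.

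The tests on the window around LCN2 and on the ratios of other genes were chosen only after the result was seen. Genes beside LCN2 rose with it in high-PAI-1 ascites: PTGES2 (0.86), PTGES2-DT (0.85), BBLN (0.76) and SLC25A25-AS1 (0.38) rose among its 10 nearest tested neighbours, and SWI5 fell (−0.24). Their mean difference, 0.25, lay at percentile 99.986 of all windows, with 1 of 7327 windows as high and the highest other at 0.264. That window was looked at because its genes were high, so the percentile does not exclude unrelated genes lying together by chance. The median ratio of the low-PAI-1 to the high-PAI-1 difference over the 4 risen neighbours was 0.465, beside 0.483 for LCN2, with 0.896 for SLC25A25-AS1 and 0.121 for SWI5. Over the 284 other genes that rose in high-PAI-1 ascites the median was 0.477, with 36.3% within 0.2 of LCN2, and both differences share the FBS arrays, so the ratio leaves open whether the neighbours follow LCN2.

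MT1G, MT1X and MT2A had far higher values in low-PAI-1 than in high-PAI-1 ascites, and MT1F was higher there by less. This could reflect zinc, glucocorticoid or oxidative stress. In high-PAI-1 ascites MT1G rose (0.67 ± 0.13) and MT1F fell (−0.37 ± 0.08) against FBS. MT1G passed the filter through its low-PAI-1 values, since it had 4.05 and 3.88 in FBS and 4.78 and 4.49 in high-PAI-1 ascites. Glucocorticoid targets had a median difference of 0.0929 between low-PAI-1 and high-PAI-1 ascites, with quartiles of −0.0812 and 0.155 over 8 genes. These values met the limits set against it, a median under 0.1 and an upper quartile under 0.2, but the median lay closer to its limit than its spread, so that explanation stays open. NRF2 targets had a median of −0.0495 and an upper quartile of −0.00368 over 8 genes, below the same limits throughout that range. Against FBS the NRF2 median was 0.158 in high-PAI-1 and 0.0628 in low-PAI-1 ascites. These values argue only against an NRF2 response behind the difference between the ascites media. Oxidative stress acting without these genes was not tested. For the rise over FBS oxidative stress stays open. The NRF2 list was past the threshold on the higher side in low-PAI-1 ascites against FBS (camera adjusted p = 0.0484, 0.134 on ranks). A metal-dependent explanation was not tested, because SLC30A1 was not analysed here.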
